A study of Mus musculus with 12 samples.

How the data were processed

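Ventral CA1 of acute horizontal brain slices from wild-type male C57BL/6J mice of 5 to 7 weeks was profiled by directional poly(A) RNA sequencing with paired-end reads of 150 bp. Per the labels' protocols, slices of 400 µm were incubated for at least 3 h, an area of 1 mm2 around the electrodes was dissected from slices frozen 30 min after stimulation, 6 slices were pooled per sample, and each mouse gave 4 slices, 1 for each group. The 12 libraries fell into 4 groups of 3. Control slices received basal stimulation only. STET slices received strong tetanization, 3 trains of 100 pulses at 100 Hz, which induces late long-term potentiation. STET_S100 and STET_S200 slices received in addition stimulation of the basolateral amygdala at 100 Hz or 200 Hz. The description of the STET_S200 samples gives 200 Hz and then, in brackets, pulses at 100 Hz, so the rate used is stated in conflicting ways, and the group is named here as in the labels. By this protocol the groups share mice, but the labels do not say that equal replicate numbers mark the same mice. The main fit, the permutations and the splits treat the 12 libraries as independent.

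The deposited values were read counts per Ensembl gene ID, with 1 column per sample, and were whole numbers with no scaling. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.1a, HTSeq 0.11.2, R 4.0.2 and limma, without their settings. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so genes are given by symbol and ID and no coordinates are printed. Of 55471 IDs, 55144 were paired with a symbol and 55230 (99.6%) were found in the GENCODE M21 annotation, which gave gene lengths and GC content. Total counts ran from 36.3 to 52.8 M per library, against 45 M reads stated in the labels. At least 1 read was counted for 35834 genes. Read counts are not counts of independent molecules, so counting error understates the spread. Pairs of libraries of the same group differed by a chi-square of 5.11 to 20.9 per degree of freedom, and the biological coefficient of variation was 8.25%.

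Counts were scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, in R 4.3.3, in 1 fit of all 12 libraries with 1 coefficient per group. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 19492. Adjusted p-values are Benjamini-Hochberg values over these genes within each comparison, with a threshold of 0.05. The 7 comparisons were each stimulated group against Control, the 3 pairs of stimulated groups, and the mean of the 3 stimulated groups against Control. Values are given as counts scaled to the adjusted library total (CPM) with the standard deviation (SD) over the 3 libraries of a group, and as log2 fold changes with the standard error (SE) of the fit. The 47 gene lists of at least 5 tested genes covered activity-regulated genes, synaptic proteins and receptors, metabolism, stress and markers of cell types. They were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera was also run with an estimated correlation, and fry was run as a test of each list by itself. Scores of a list are the mean log2 CPM of its genes in a library, and were compared between groups by two-sided permutation tests.

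The groups, comparisons, tests, lists and most other settings were chosen before the data were examined. So was the rule for the named genes. It takes the genes with the largest changes among those past the threshold or, where none passed, the 5 higher and 5 lower genes with the smallest p at a mean log2 CPM of at least 0, given as values that did not pass. It also takes 15 activity-regulated genes in the comparisons with Control whatever their p, and up to 4 members of each list described. Predicted genes are named only where they are among the first 3 in their direction. The other settings chosen then were other scalings (RLE and upper quartile), no filter or a mean count of at least 10, DESeq2 1.42.0, limma-voom with and without sample quality weights, fits without robust dispersion, fits of the compared groups alone, the replicate number as a block, a threshold of 0.1, and leaving out each library in turn. After the data were seen, 5 settings were added. They were a term for the 5 libraries with RNA of peripheral tissues, a choroid plexus score as a covariate, both terms together, the 7 other libraries alone, and DESeq2 with its default filtering level of 0.1.

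The tests were tried on simulated data for STET against Control, made from the means and library sizes of the 12 libraries with 200 of 19492 genes changed. Counts were drawn for each gene independently, with no differences between libraries shared by many genes. edgeR recovered 82.1% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls. DESeq2 recovered 86.6% at 1.5-fold with 26 false calls. A list of 30 genes raised 1.2-fold was called by camera with the preset correlation (adjusted p = 4.12e-20), with an estimated correlation (adjusted p = 0.00165) and by fry (adjusted p = 1.26e-04). Fry also called 6 of the 47 other lists. The changed genes were drawn without leaving out members of these lists, so the 6 are not known to be false calls. Python 3.11.15 and matplotlib 3.10.9 were used for tables and figures. No library was left out.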

Results

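Gene expression in ventral CA1 was measured 30 min after the stimulation of acute mouse brain slices in 12 RNA sequencing libraries, each from 6 pooled slices. The 4 groups of 3 libraries were Control, with basal stimulation only, STET, with strong tetanization that induces late long-term potentiation, and STET_S100 and STET_S200, in which the tetanization was joined by stimulation of the basolateral amygdala. Total counts per library averaged 42.1 M in Control, 46.6 M in STET, 46.6 M in STET_S100 and 41.4 M in STET_S200, with a range of 36.3 to 52.8 M. The series design names the question as the transcriptional state after late potentiation alone or with amygdala stimulation at either rate.

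The libraries differed in transcripts known as markers of the choroid plexus or of tissues outside the brain. Ttr, the thyroid hormone carrier made by the choroid plexus, ran from 1.73 to 2798 CPM, and all 3 STET_S200 libraries and STET_S100 3 were low in it. Fabp4, a fatty acid carrier of fat cells and capillaries, lay between 7.08 and 8.46 CPM in Control 3, STET 3, STET_S100 1, STET_S200 2 and STET_S200 3 and at no more than 0.275 CPM in the 7 other libraries. Alb, the serum albumin made by the liver, reached 7.49 to 8.47 CPM in 4 of those 5 libraries and 0.0868 CPM in STET 3. These levels are small shares of each library, but they part the libraries across the groups, with 1 such library in Control, 1 in STET, 1 in STET_S100 and 2 in STET_S200. The 7 others are called below those without peripheral-tissue RNA, which means only that Fabp4 was not above 1 CPM. Control 1 and Control 2, which are among them, held the kidney transcripts Umod (0.718 and 0.382 CPM) and Slc34a1 (0.359 and 0.491 CPM). STET 3 held these kidney transcripts as well, Umod at 0.477 CPM and Slc34a1 at 0.521 CPM.

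**Figure D1:**
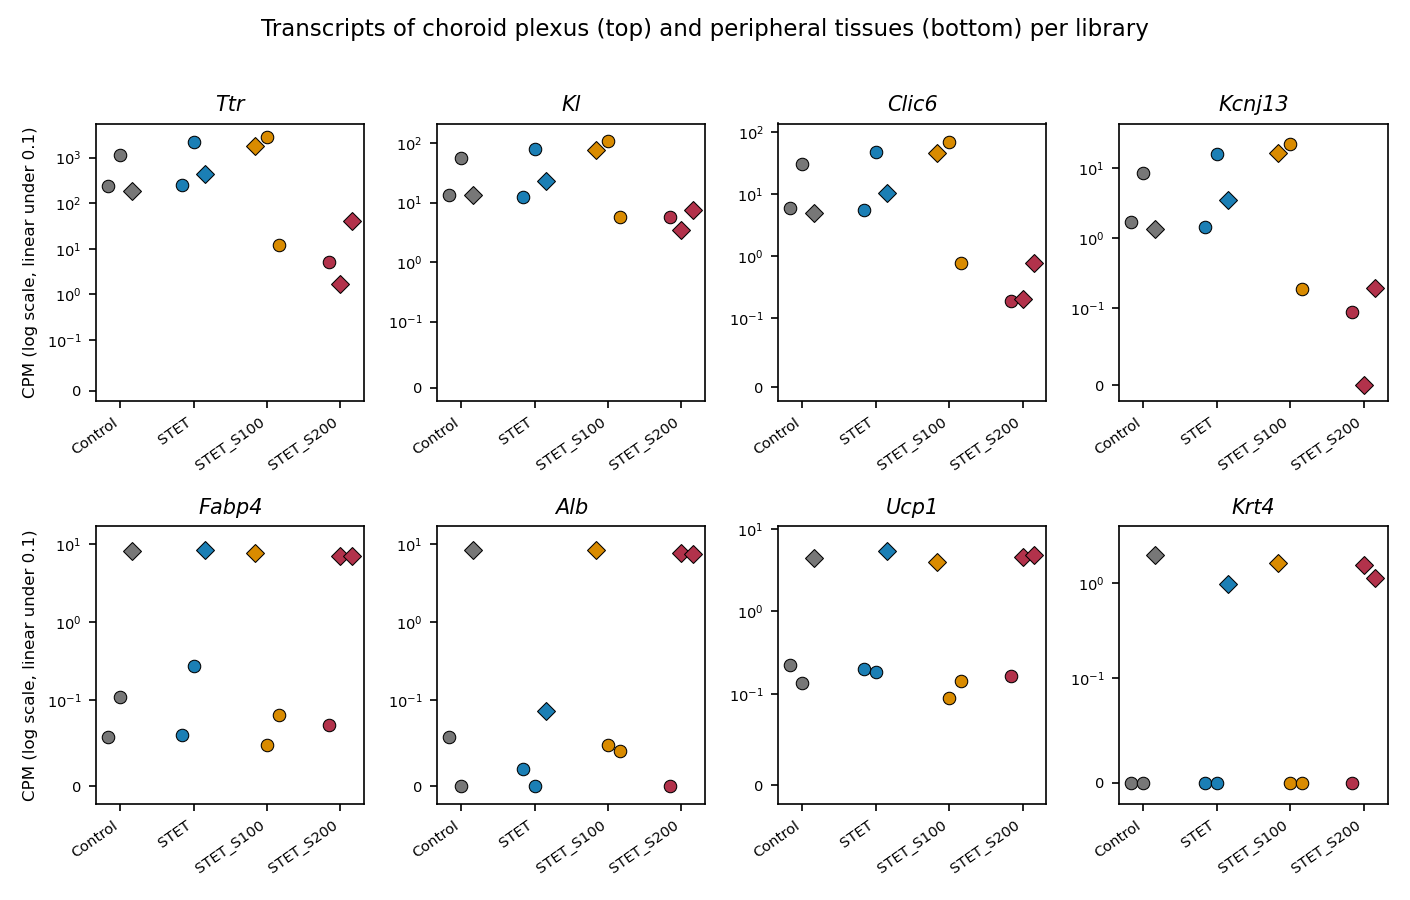
CPM per library (vertical axis, logarithmic and linear under 0.1) of 4 choroid plexus genes (top) and 4 genes of peripheral tissues (bottom) in the 4 groups (horizontal axis), with 1 symbol per library. Diamonds mark the 5 libraries with Fabp4 above 1 CPM, and Ttr runs from 1.73 to 2798 CPM.

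Tetanization alone was compared with basal stimulation first. Arc (ENSMUSG00000022602), a regulator of AMPA receptor endocytosis, averaged 258 ± 57.9 CPM in STET and 96.7 ± 17.6 CPM in Control (SD, n = 3 each), a log2 fold change of 1.42 ± 0.33 (SE). Npas4 (ENSMUSG00000045903), a transcription factor induced by calcium entry in neurons, averaged 210 ± 49.2 CPM against 63.8 ± 10.5 CPM, a log2 fold change of 1.72 ± 0.41. Fos was at 263 ± 47.9 CPM against 157 ± 9.51 CPM, Junb at 276 ± 13.4 against 191 ± 15.0 CPM and the growth arrest gene Gadd45g (ENSMUSG00000021453) at 86.0 ± 3.16 against 53.1 ± 6.89 CPM, and in each of these 5 genes all 3 STET libraries lay above all 3 Control libraries. The log2 fold changes of Egr1 (0.44), Egr2 (0.55), Egr4 (0.45), Nr4a1 (0.43), Dusp1 (0.43) and Fosb (0.21) were positive without overlap between the groups. Bdnf (0.07 ± 0.24), Homer1 (−0.05 ± 0.08), Nptx2 (0.24 ± 0.14) and Inhba (0.29 ± 0.41) overlapped with Control. Nr4a2, a nuclear receptor gene, was lower in all 3 STET libraries (−0.18 ± 0.07). None of these single genes passed the threshold over all genes (adjusted p = 1.00 for each). The other genes with the smallest p were Gm45743 (0.96) and the ribosomal pseudogene Rpl17-ps10 (0.75), whose reads may be shared with its parent gene, on the higher side, and the septin gene Sept5 (−0.23), the opioid receptor gene Oprm1 (−0.59), the neuromedin B receptor gene Nmbr (−0.64), Ttyh3 (−0.12) and Mpzl2 (−1.01) on the lower side.

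The list of rapid immediate early genes rose in STET, with a median log2 fold change of 0.23 and 24 of 28 genes positive (camera adjusted p = 1.18e-11 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.815). Over all genes 0 passed, and adjusted over the list alone 2 passed, Arc and Npas4. This count became 0 without Control 1, Control 2, Control 3, STET 1 or STET 2, and 7 without STET 3. With only the 7 libraries without peripheral-tissue RNA it was 11. It was 0 with the choroid score, 1 with the replicate number as a block, 10 with DESeq2 and 12 with limma-voom or without robust dispersion. In the main fit the prior degrees of freedom, the weight of the spread shared over genes, were 0.157 for Arc and 0.190 for Fos. Their median over genes was 8.90, so the robust fit let these 2 genes borrow little from the others.

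Ribosomal protein genes were also higher in STET. Of 79 genes 73 were positive, the median log2 fold change was 0.06, and Rps27 (0.19), Rpl37a (0.17), Rpl38 (0.17) and Rps21 (0.15) gave examples (camera adjusted p = 8.59e-13 for the list, and adjusted p = 0.815 with an estimated correlation). The oxidative phosphorylation list rose with a median of 0.05 and 52 of 63 genes positive (adjusted p = 6.38e-07, and 0.815 as the adjusted p with an estimated correlation). Genes of presynaptic release fell, with a median of −0.05 and 5 of 33 genes positive, among them the synapsin gene Syn3 (−0.27) and the active zone scaffold Pclo (−0.13) on the lower side (adjusted p = 5.02e-04, and adjusted p = 0.815 with an estimated correlation). With the 7 libraries alone the presynaptic call was lost (adjusted p = 0.0828). In each of these 3 lists 0 genes passed adjusted over the list alone, and 0 over all genes. The inflammation list rose with a median of 0.15 and 30 of 32 genes positive, the higher ones including the chemokine genes Ccl12 (0.59), Ccl4 (0.40) and Cxcl2 (0.24) and the NF-kappa-B regulator Nfkbiz (0.30), with an adjusted p of 3.95e-06, and an adjusted p of 0.815 with an estimated correlation. Of its genes 0 passed adjusted over the list alone and 0 over all genes. This call ended without Control 3 (adjusted p = 0.0666) and with the 7 libraries alone (adjusted p = 0.912).

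Further lists that rose in STET were delayed activity-regulated genes (median 0.07, adjusted p = 0.0313), genes of MAP kinase feedback (median 0.12, adjusted p = 0.0459), reactive astrocyte genes (median 0.10, adjusted p = 0.0313) and oligodendrocyte markers (median 0.06, adjusted p = 0.0313). Those that fell were plasticity kinases (median −0.03, adjusted p = 0.00831), glutamate receptor genes (median −0.03, adjusted p = 0.0233) and postsynaptic scaffold genes (median −0.03, adjusted p = 0.0170). Each had an adjusted p of 0.815 with an estimated correlation. Of their genes 1 passed adjusted over the list alone, Gadd45g, and 0 over all genes. The delayed call ended without Control 3 (0.862), STET 2 (0.446) or STET 3 (0.102) and with the 7 libraries (0.978). The MAP kinase call ended without Control 3 (0.704) or STET 2 (0.418) and with the replicate number as a block (0.0625), the choroid score (0.0696) or the 7 libraries (0.413). The reactive astrocyte call ended without Control 2 (0.615), Control 3 (0.518), STET 2 (0.321) or STET 3 (0.447) and with the 7 libraries (0.718). The oligodendrocyte call ended without Control 2 (0.969) or STET 2 (0.838) and with the choroid score (0.0640). The plasticity kinase call ended without Control 2 (0.0734) or STET 2 (0.0628) and with the 7 libraries (0.0828). The glutamate receptor call ended without Control 2 (0.209), Control 3 (0.0666), STET 2 (0.121) or STET 3 (0.0736) and with the 7 libraries (0.204). The postsynaptic scaffold call ended without Control 2 (0.555) or STET 2 (0.0628) and with the 7 libraries (0.161).

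**Figure D2:**
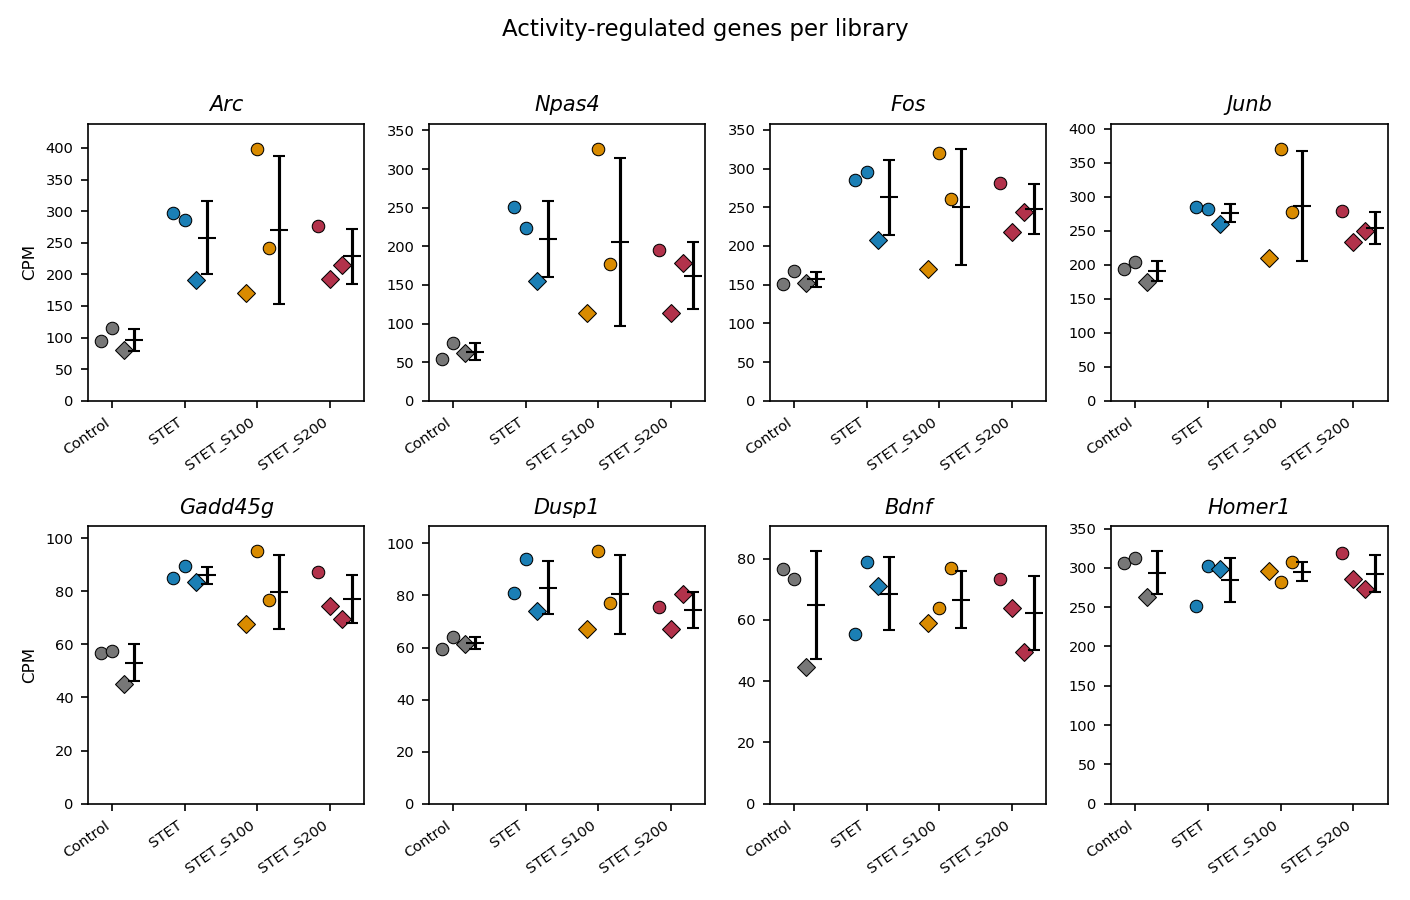
CPM (vertical axis) of 8 activity-regulated genes in the 4 groups (horizontal axis), with 1 symbol per library, diamonds for the 5 libraries with RNA of peripheral tissues, and bars for the mean ± SD (n = 3). Arc averages 96.7 CPM in Control and 228 to 270 CPM in the stimulated groups, whereas Homer1 averages 284 to 295 CPM in all 4 groups.

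Tetanization joined by 100 Hz amygdala stimulation was compared with Control next. Arc averaged 270 ± 117 CPM and Npas4 206 ± 109 CPM in STET_S100 (SD, n = 3), log2 fold changes of 1.48 ± 0.33 and 1.69 ± 0.41 over Control. Fos (0.67 ± 0.23), Junb (0.58 ± 0.18) and Dusp1 (0.38 ± 0.14) were also higher in all 3 libraries, Nr4a2 (−0.15 ± 0.07) was lower in all 3, and Egr1 (0.48), Egr2 (0.46), Egr4 (0.39), Nr4a1 (0.44), Fosb (0.17), Nptx2 (0.33), Inhba (0.47), Bdnf (0.03) and Homer1 (0.01) overlapped with Control. The genes with the smallest p were Sstr3 (ENSMUSG00000044933), a somatostatin receptor of neuronal cilia, at 35.3 ± 1.15 against 28.4 ± 2.21 CPM (log2 fold change 0.31 ± 0.06), and Ubtd1 (0.38), Cdc40 (0.22), the neuronal transcription factor Neurod2 (0.16) and the mitochondrial calcium uniporter Mcu (0.19). On the lower side they were the complex I subunit Ndufb9 (−0.35 ± 0.07), B930095G15Rik (−0.19), Gm10736 (−0.26), Gli3 (−0.31) and Rnf169 (−0.22). None of these genes passed over all genes, the smallest adjusted p being 0.902.

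The rapid immediate early genes rose as a list in STET_S100, with a median of 0.19 and 23 of 28 positive (camera adjusted p = 3.66e-06, and adjusted p = 0.927 with an estimated correlation). Beside 0 over all genes, 3 passed adjusted over the list alone, Arc, Npas4 and Btg2 (1.18), a transcriptional regulator that slows proliferation. The count was 0 without Control 1, Control 2, Control 3, STET_S100 2 or STET_S100 3, 14 without STET_S100 1 and 13 with the 7 libraries alone. It was 0 with the choroid score or the compared groups alone, 9 with limma-voom, 10 with DESeq2 and 11 without robust dispersion. Arc stood at 170 to 215 CPM in the 4 stimulated libraries with peripheral-tissue RNA and at 241 to 399 CPM in the 5 without. Microglia markers fell, with a median of −0.11 and 1 of 17 positive, P2ry12 at −0.31 and Tmem119 at −0.34 (adjusted p = 0.00408, and adjusted p = 0.927 with an estimated correlation; 0 genes adjusted over the list alone and over all genes). This call ended without Control 2 (adjusted p = 0.0880), STET_S100 2 (0.102) or STET_S100 3 (0.0951).

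In STET_S100 the further lists that rose were delayed activity-regulated genes (median 0.06, adjusted p = 0.0427), genes of MAP kinase feedback (median 0.06, adjusted p = 0.0439), interferon genes (median 0.11, adjusted p = 0.0273) and reactive astrocyte genes (median 0.15, adjusted p = 0.0252). Those that fell were glutamate receptor genes (median −0.01, adjusted p = 0.0439), presynaptic release genes (median −0.05, adjusted p = 0.00733), mitochondrially encoded genes (median −0.10, adjusted p = 0.0350) and astrocyte markers (median −0.06, adjusted p = 0.0350). The adjusted p with an estimated correlation was 0.927 for each. Of their genes 2 passed adjusted over the list alone, Shisa9 (−0.19) and Grin2b (−0.14), both lower, and 0 over all genes. The delayed call ended without Control 3 (0.702), STET_S100 2 (0.173) or STET_S100 3 (0.296) and with the replicate number as a block (0.0550), the choroid score (0.0614) or the 7 libraries (0.183). The MAP kinase call ended without Control 3 (0.521), STET_S100 2 (0.182) or STET_S100 3 (0.296) and with the block (0.0550), the choroid score (0.0717) or the 7 libraries (0.0706). The interferon call ended without Control 2 (0.216), Control 3 (0.313) or STET_S100 2 (0.339) and with the 7 libraries (0.184). The reactive astrocyte call ended without Control 2 (0.248), Control 3 (0.330) or STET_S100 3 (0.0867) and with the 7 libraries (0.603). The glutamate receptor call ended without Control 2 (0.212), Control 3 (0.137), STET_S100 1 (0.373) or STET_S100 2 (0.102) and with the block (0.0512), the choroid score (0.0654) or the 7 libraries (0.603). The presynaptic call ended without STET_S100 1 (0.140) or STET_S100 2 (0.102) and with the 7 libraries (0.164). The mitochondrial call ended without Control 2 (0.516) or STET_S100 2 (0.615) and with the block (0.0512). The astrocyte call ended without Control 2 (0.780) or STET_S100 2 (0.377) and with the block (0.0512).

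In STET_S200, with 200 Hz stimulation of the amygdala, Arc averaged 228 ± 43.6 CPM and Npas4 162 ± 43.1 CPM (SD, n = 3), log2 fold changes of 1.24 ± 0.33 and 1.35 ± 0.41 over Control. Fos (0.66), Junb (0.41), Egr2 (0.49), Egr4 (0.31) and Dusp1 (0.27) were higher in all 3 libraries, Egr1 (0.33), Nr4a1 (0.19), Fosb (0.02), Nptx2 (0.33), Inhba (0.40), Bdnf (−0.06) and Homer1 (−0.01) overlapped with Control, and Nr4a2 (−0.23) was lower in all 3. Sstr3 was at 36.8 ± 2.21 CPM (log2 fold change 0.37 ± 0.06), Neurod2 (ENSMUSG00000038255) at 148 ± 3.45 against 127 ± 1.04 CPM (0.22 ± 0.04), and the lipase gene Lpl (0.40), the glypican gene Gpc1 (0.20) and Nifk (0.24) were also higher in all 3. Igfbp5 (ENSMUSG00000026185), which binds insulin-like growth factors, was lower at 103 ± 7.52 against 127 ± 2.95 CPM (−0.31 ± 0.06), as were Slc16a11 (−0.48), Otof (−0.50), the cortical transcription factor Cux2 (−0.26) and Plppr3 (−0.21). None passed with edgeR, with adjusted p = 0.218 for Sstr3, 0.220 for Neurod2 and 0.256 for Igfbp5. DESeq2 called 4 genes, Sstr3, Neurod2, Igfbp5 and Lpl, with adjusted p of 0.00116, 0.00116, 0.00635 and 0.00857. Without STET_S200 3 edgeR called 2 genes, Sstr3 and Zfp36l1.

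The rapid immediate early genes rose as a list in STET_S200, with a median of 0.14 and 20 of 28 positive (camera adjusted p = 0.00303, and adjusted p = 0.902 with an estimated correlation), and the call ended without STET_S200 1 (adjusted p = 0.0857). Of its genes 0 passed adjusted over the list alone and over all genes, with 1 over the list alone without Control 1, 3 with the 7 libraries, 6 with limma-voom, 7 with DESeq2 and 8 without robust dispersion. Microglia markers fell, with a median of −0.18 and 1 of 17 positive, including Tmem119 (−0.64) and the signalling adaptor Tyrobp (−0.24) (adjusted p = 1.06e-05, and adjusted p = 0.902 with an estimated correlation). With the 7 libraries alone, where STET_S200 is 1 library, the microglia call was lost (adjusted p = 0.193). Choroid plexus and ependymal markers fell with a median of −2.28 and 3 of 14 positive, Ttr being at −5.10 (adjusted p = 0.00303, and adjusted p = 0.902 with an estimated correlation). This call was also lost with the 7 libraries (adjusted p = 0.139). Adjusted over the list alone 0 genes passed in the microglia and choroid lists, and 0 over all genes.

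Also rising in STET_S200 were inflammation genes (median 0.16, adjusted p = 0.00559) and ubiquitin and proteasome genes (median 0.03, adjusted p = 0.0147). Those that fell were circadian genes (median −0.07, adjusted p = 0.0261) and astrocyte markers (median −0.06, adjusted p = 0.0261). Each had an adjusted p of 0.902 with an estimated correlation. Of their genes 1 passed adjusted over the list alone, Per1 (−0.23), and 0 over all genes. The choroid score did not overlap between STET_S200 (−1.84 to 0.184) and Control (2.08 to 4.55). Where a call ended with that score, choroid content therefore cannot be told apart from the group. The inflammation call ended without Control 3 (0.541), STET_S200 1 (0.209) or STET_S200 2 (0.0926). The proteasome call ended without Control 2 (0.199) or STET_S200 1 (0.0544) and with the choroid score (0.599) or the 7 libraries (0.118). The circadian call ended without Control 1 (0.0680), Control 2 (0.0535) or STET_S200 3 (0.117) and with the peripheral-tissue term (0.0660) or the 7 libraries (0.503). The astrocyte call ended without Control 2 (0.630), STET_S200 2 (0.118) or STET_S200 3 (0.696) and with the peripheral-tissue term (0.108), the choroid score (0.158) or the 7 libraries (0.580).

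When the 9 stimulated libraries were set against Control, Arc (1.38 ± 0.29), Npas4 (1.59 ± 0.36), Fos (0.69 ± 0.20), Junb (0.51 ± 0.15), Dusp1 (0.36 ± 0.12), Gadd45g (0.60 ± 0.12) and Sstr3 (0.28 ± 0.05) were higher in all 9 than in each Control library (log2 fold change ± SE). Igfbp5 (−0.23), Otof (−0.41), Sept5 (−0.19) and Nr4a2 (−0.18) were lower in all 9. Over all genes, the 9 libraries and Control did not overlap for 193 (0.990%), where chance gives 0.909%. Egr1 (0.42), Egr2 (0.50), Egr4 (0.38), Nr4a1 (0.35), Fosb (0.14), Nptx2 (0.30), Inhba (0.39), Bdnf (0.02) and Homer1 (−0.02) overlapped with Control, as did Neurod2 (0.13), Cdc40 (0.17), Ubtd1 (0.28), Ylpm1 (−0.17) and Rnf169 (−0.17). None passed over all genes with edgeR (smallest adjusted p = 0.810), and DESeq2 called Gadd45g, Arc, Sstr3, Npas4 and Igfbp5.

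The rapid immediate early genes rose as a list in the stimulated libraries, with a median of 0.14 and 22 of 28 positive (camera adjusted p = 3.71e-08, and adjusted p = 0.955 with an estimated correlation). Adjusted over the list alone 9 passed, Arc, Npas4, Btg2 (1.06), Ier2 (0.48), Zfp36 (0.32), Fos, Junb, Jun (0.28) and Dusp1, against 0 over all genes. This count was 0 without Control 1, Control 3, STET 1 or STET_S200 1, 5 without Control 2, 4 without STET 2 or STET_S200 3, 3 without STET_S100 3, and 14 without STET_S100 1, and 13 with the 7 libraries alone. The score of the list was higher by 0.305 than in Control (exact two-sided permutation p = 0.0136 over 220 splits, 0.641 adjusted over the 47 lists), with 8 of 9 stimulated libraries above all Control libraries. The splits took no account of the replicate numbers or of mice shared between the groups. Over the 4 groups together the permutation p of the score was 0.0888. Microglia markers fell with a median of −0.10 and 3 of 17 positive (camera adjusted p = 6.33e-04, and adjusted p = 0.955 with an estimated correlation; 0 genes adjusted over the list alone and 0 over all genes), and the call ended without Control 2 (adjusted p = 0.0849).

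In all stimulated libraries against Control, the further lists that rose were inflammation genes (median 0.08, adjusted p = 0.00846), genes of MAP kinase feedback (median 0.06, adjusted p = 0.0434) and reactive astrocyte genes (median 0.15, adjusted p = 0.0109). Presynaptic release genes fell (median −0.03, adjusted p = 0.0109). The adjusted p with an estimated correlation was 0.955 for each. Of their genes 0 passed adjusted over the list alone and 0 over all genes. The inflammation call ended without Control 3 (0.739) or STET_S100 2 (0.0521) and with the 7 libraries (0.143). MAP kinase genes lost their call without Control 3 (0.644), STET 2 (0.133), STET_S100 2 (0.0610), STET_S100 3 (0.0709) or STET_S200 1 (0.126) and with the replicate number as a block (0.0578), the choroid score (0.0512) or the 7 libraries (0.0593). The reactive astrocyte call ended without Control 2 (0.474) or Control 3 (0.441) and with the 7 libraries (0.461). The presynaptic call ended without Control 1 (0.1002), STET_S100 1 (0.0575) or STET_S100 2 (0.0521) and with the 7 libraries (0.0602).

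**Figure D3:**
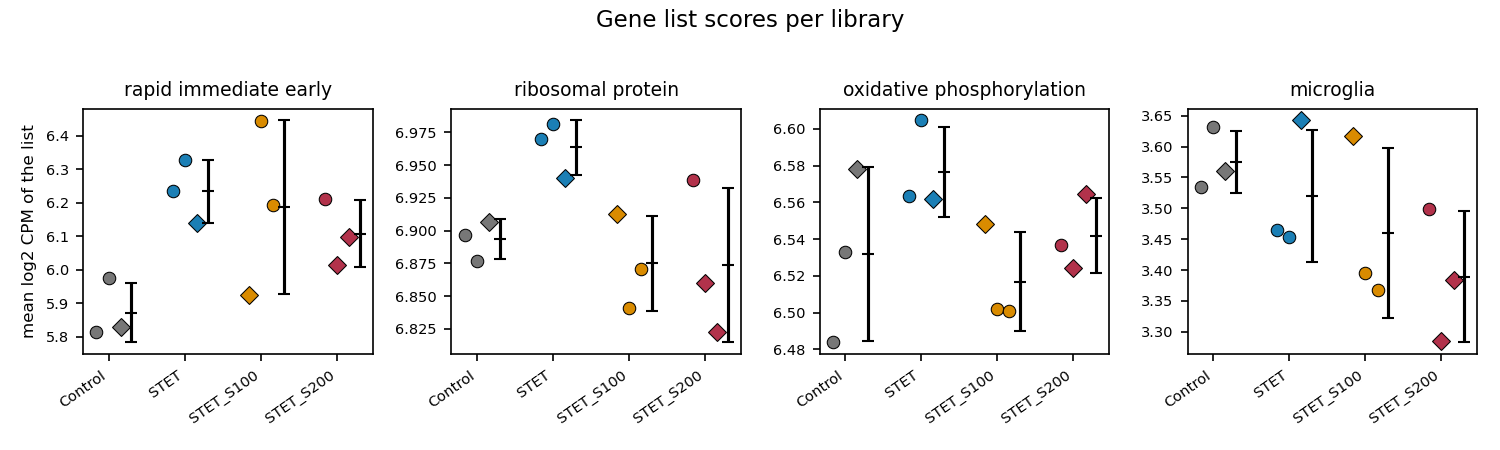
Mean log2 CPM of 4 gene lists (vertical axes) per library in the 4 groups (horizontal axis), with diamonds for the 5 libraries with RNA of peripheral tissues and bars for the mean ± SD (n = 3). For the rapid immediate early list, 8 of the 9 stimulated libraries lie above all 3 Control libraries.

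The addition of 100 Hz amygdala stimulation to tetanization was assessed by comparing STET_S100 with STET. Ribosomal protein genes fell, with 4 of 79 positive and a median of −0.08. Rps29 (ENSMUSG00000034892) averaged 178 ± 9.14 CPM in STET_S100, 227 ± 14.4 CPM in STET and 209 ± 18.7 CPM in Control (SD, n = 3), a log2 fold change of −0.36 ± 0.06 between the first 2, and Rpl38 (−0.25), Rpl39 (−0.25) and Rps28 (−0.23) were lower without overlap. The list passed with camera (adjusted p = 3.2e-23), and the adjusted p was 0.967 with an estimated correlation. Of its genes 15 passed adjusted over the list alone, all lower, against 0 over all genes (adjusted p = 0.614 for Rps29 with edgeR, and 9.17e-04 with DESeq2). Oxidative phosphorylation genes fell with a median of −0.06 and 11 of 63 positive, with 7 lower adjusted over the list alone, among them Ndufb10 (−0.16), Atp5e (−0.20), Cox7c (−0.16) and Cox6c (−0.15), and 0 over all genes (adjusted p = 1.46e-10, and adjusted p = 0.967 with an estimated correlation). Markers of CA3 and CA2 rose with a median of 0.21 and 11 of 12 positive, among them Amigo2 (0.47) and the kainate receptor subunit Grik4 (0.22) (adjusted p = 9.91e-04, and adjusted p = 0.967 with an estimated correlation), with 0 adjusted over the list alone and over all genes. With the 7 libraries alone the CA3 and CA2 call was lost (adjusted p = 0.0920). Inflammation genes fell with a median of −0.18 and 5 of 32 positive, Cxcl2 (−0.43) passing adjusted over the list alone, 0 passing over all genes and Tnf at −0.43 (adjusted p = 1.92e-05, and adjusted p = 0.967 with an estimated correlation). That call ended without STET_S100 1 (adjusted p = 0.0595) and with the 7 libraries (adjusted p = 0.945). Oligodendrocyte (median −0.13), astrocyte (−0.05) and microglia (−0.08) markers and mitochondrially encoded genes (−0.11) fell as well, with adjusted p of 0.00501, 0.0326, 0.0212 and 0.00187. With an estimated correlation each had an adjusted p of 0.967, and in each 0 genes passed adjusted over the list alone and over all genes. The oligodendrocyte call ended without STET 2 (0.570) or STET_S100 1 (0.0633), and the astrocyte call without STET 2 (0.140), STET 3 (0.291), STET_S100 2 (0.554) or STET_S100 3 (0.0502). The microglia call ended without STET 3 (0.603), STET_S100 2 (0.364) or STET_S100 3 (0.422), and the mitochondrial call without STET 2 (0.0772) or STET_S100 2 (0.277). The astrocyte call also ended with the replicate number as a block (0.0552) and with the 7 libraries (0.0892). The higher genes with the smallest p were Neurod2 (0.14), the deacetylase gene Hdac4 (0.15), the Wnt pathway receptor Lgr5 (0.58), Ahdc1 (0.15) and Adamts14 (0.92), of which none passed.

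Adding 200 Hz amygdala stimulation was assessed by comparing STET_S200 with STET. Ribosomal protein genes fell here as well, with 4 of 79 positive and a median of −0.08, and with Rps27 at −0.28 ± 0.06, Rpl38 at −0.24 ± 0.05, Rps29 at −0.27 ± 0.06 and Rps21 at −0.22 ± 0.05 (log2 fold change ± SE). Adjusted over the list alone 17 passed, all lower, against 0 over all genes (camera adjusted p = 1.31e-18, and adjusted p = 0.646 with an estimated correlation). With the 7 libraries alone the list did not pass (adjusted p = 0.224). Microglia markers fell with a median of −0.11 and 1 of 17 positive (adjusted p = 1.99e-04, and adjusted p = 0.646 with an estimated correlation), and choroid plexus markers fell with a median of −2.77 and 3 of 14 positive (adjusted p = 8.16e-04, and adjusted p = 0.646 with an estimated correlation). The choroid call ended without STET 2 (adjusted p = 0.154), and with the 7 libraries neither list passed (adjusted p = 0.458 for microglia and 0.0732 for choroid). With the choroid score as a covariate the microglia call ended (adjusted p = 0.360). Of the 16 lists called in this comparison, 2 then still passed, the ribosomal and pyramidal lists. The choroid score ran from −1.84 to 0.184 in STET_S200 and from 2.14 to 5.14 in STET, so the covariate itself parts these groups. Where a call of this comparison ended with it, choroid content therefore cannot be told apart from the group. Astrocyte (median −0.04), endothelial (−0.11) and nuclear RNA (−0.17, with Malat1 at −0.35) lists fell too, and pyramidal neuron markers (0.05) rose. Their adjusted p were 0.0226, 0.0113, 0.0113 and 0.0146, and each had an adjusted p of at least 0.646 with an estimated correlation. The astrocyte call ended without STET 2 (0.0873), STET 3 (0.183), STET_S200 2 (0.167) or STET_S200 3 (0.715) and with the choroid score (0.393) or the peripheral-tissue term (0.122). That list passed in the other direction with the 7 libraries (0.0288). The endothelial call ended without STET 3 (0.183) or STET_S200 1 (0.0575), with the choroid score (0.360) and with the 7 libraries (0.224). The nuclear RNA call ended without STET_S200 1 (0.357) and with the choroid score (0.450). The pyramidal call ended without STET 3 (0.0648), STET_S200 1 (0.0544) or STET_S200 3 (0.0863) and with the 7 libraries (0.171). Of the genes of these 4 lists, 2 pyramidal genes passed adjusted over the list alone, Neurod2 and Nptx1 (0.18), and 0 over all genes. Receptors for neuromodulators rose with a median of 0.08 and 27 of 35 positive, the nicotinic receptor subunit Chrna7 at 0.16 (adjusted p = 0.00131, and adjusted p = 0.646 with an estimated correlation), a call that ended without STET_S200 3 (adjusted p = 0.113), with the 7 libraries (adjusted p = 0.505) and with the choroid score as a covariate (adjusted p = 0.283). In each of the microglia, choroid and neuromodulator receptor lists 0 genes passed adjusted over the list alone and 0 over all genes. Neurod2 (0.21 ± 0.04), the ephrin gene Efna3 (0.17), Sstr3 (0.23), Lgr5 (0.64) and the protocadherin gene Pcdhac2 (0.19) were the higher genes with the smallest p, and the calcium-binding protein gene S100a1 (−0.30 ± 0.06), Gm43279 (−0.62) and the ribosomal pseudogene Rpl38-ps2 (−0.48), whose reads may be shared with Rpl38, were lower. None passed with edgeR (smallest adjusted p = 0.857).

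The other lists that rose in STET_S200 against STET were plasticity kinases (median 0.04, adjusted p = 0.0314), glutamate receptor genes (median 0.06, adjusted p = 0.0348), inhibitory synapse genes (median 0.06, adjusted p = 0.0113), postsynaptic scaffold genes (median 0.04, adjusted p = 0.00754) and presynaptic release genes (median 0.04, adjusted p = 0.0162). Rapid immediate early genes fell, with 3 of 28 positive (median −0.12, adjusted p = 0.00754) and Per1 at −0.22, as did oxidative phosphorylation genes (median −0.04, adjusted p = 0.00497). With an estimated correlation the adjusted p was 0.646 or 0.666 for each. In each 0 genes passed adjusted over the list alone and 0 over all genes. The plasticity kinase call ended without STET 2 (0.0873), STET 3 (0.126), STET_S200 1 (0.219) or STET_S200 3 (0.0616) and with the choroid score (0.908) or the 7 libraries (0.0934). The glutamate receptor call ended without STET 2 (0.0873), STET 3 (0.133), STET_S200 2 (0.0526) or STET_S200 3 (0.305) and with the choroid score (0.596) or the 7 libraries (0.885). The inhibitory synapse call ended without STET_S200 1 (0.0871) and with the choroid score (0.908) or the 7 libraries (0.0683). The postsynaptic scaffold call ended without STET_S200 1 (0.0555) and with the choroid score (0.117) or the 7 libraries (0.0735). The presynaptic call ended without STET 2 (0.0954), STET 3 (0.232) or STET_S200 3 (0.578) and with the choroid score (0.819) or the 7 libraries (0.885). The rapid immediate early call ended without STET 2 (0.117) or STET_S200 2 (0.114) and with the peripheral-tissue term (0.183), the choroid score (0.556) or the 7 libraries (0.505). The oxidative phosphorylation call ended without STET 2 (0.0954) or STET_S200 2 (0.155) and with the choroid score (0.603).

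The rate of amygdala stimulation was the question behind the comparison of STET_S200 with STET_S100. Choroid plexus markers fell in STET_S200 with a median of −3.49 and 0 of 14 positive, the chloride channel protein gene Clic6 at −6.70 (adjusted p = 9.34e-07, and adjusted p = 0.777 with an estimated correlation), with 4 passing adjusted over the list alone, all lower, and 0 over all genes. The call was lost with the 7 libraries (adjusted p = 0.0861) and with the choroid score (adjusted p = 0.559), a term that takes up its signal. The NF-kappa-B inhibitor Tnfaip3 was at 49.4 ± 4.71 CPM in STET_S200 and 40.3 ± 3.30 CPM in STET_S100 (SD, n = 3; log2 fold change 0.30 ± 0.07), and Tnfaip2 (0.49), Gm12408 (0.85), the noncoding gene Dubr (0.31) and the cadherin gene Cdh11 (0.15) were higher in all 3. The kinase gene Wnk4 (−1.42 ± 0.31) at 0.563 against 1.51 CPM, Cux2 (−0.27), Mpp7 (−0.56), Iqub (−1.36) and the receptor gene Ror1 (−0.43) were lower in all 3. None passed (smallest adjusted p = 0.956), and leaving out STET_S100 3 gave 8 genes, all lower, with Zic1, Slc26a7, Iqub and Fam81b among them. STET_S100 3 was the library of its group low in Ttr, at 12.2 CPM against 1841 and 2798 CPM. Without it, STET_S100 libraries rich in Ttr stood against STET_S200 libraries low in it. Iqub was at 2.71, 3.97 and 1.43 CPM in STET_S100 1, 2 and 3. In the same order Wnk4 was at 1.51, 2.11 and 0.909 CPM and Mpp7 at 6.62, 7.92 and 5.70 CPM. Cux2 (23.8, 24.7 and 22.1 CPM) was also lowest in STET_S100 3, and Ror1 (5.72, 7.37 and 6.08 CPM) was not. For the calls without STET_S100 3, and for Wnk4, Mpp7 and Iqub, choroid plexus content cannot be told apart from the rate of stimulation.

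Against STET_S100 the lists that rose were inflammation genes (median 0.08, adjusted p = 0.0182), oxidative phosphorylation genes (median 0.02, adjusted p = 0.0368) and receptors for neuromodulators (median 0.07, adjusted p = 0.0368). Each had an adjusted p of 0.777 with an estimated correlation. Of their genes 1 passed adjusted over the list alone, Tnfaip3, and 0 over all genes. The inflammation call ended without STET_S100 1 (0.335), STET_S200 1 (0.185) or STET_S200 2 (0.126). The oxidative phosphorylation call ended without STET_S100 2 (0.271), STET_S100 3 (0.134) or STET_S200 3 (0.351) and with the replicate number as a block (0.0523) or the peripheral-tissue term (0.121). The neuromodulator receptor call ended without STET_S100 1 (0.0630), STET_S100 2 (0.151) or STET_S200 3 (0.486) and with the choroid score (0.559) or the 7 libraries (0.533).

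**Figure D4:**
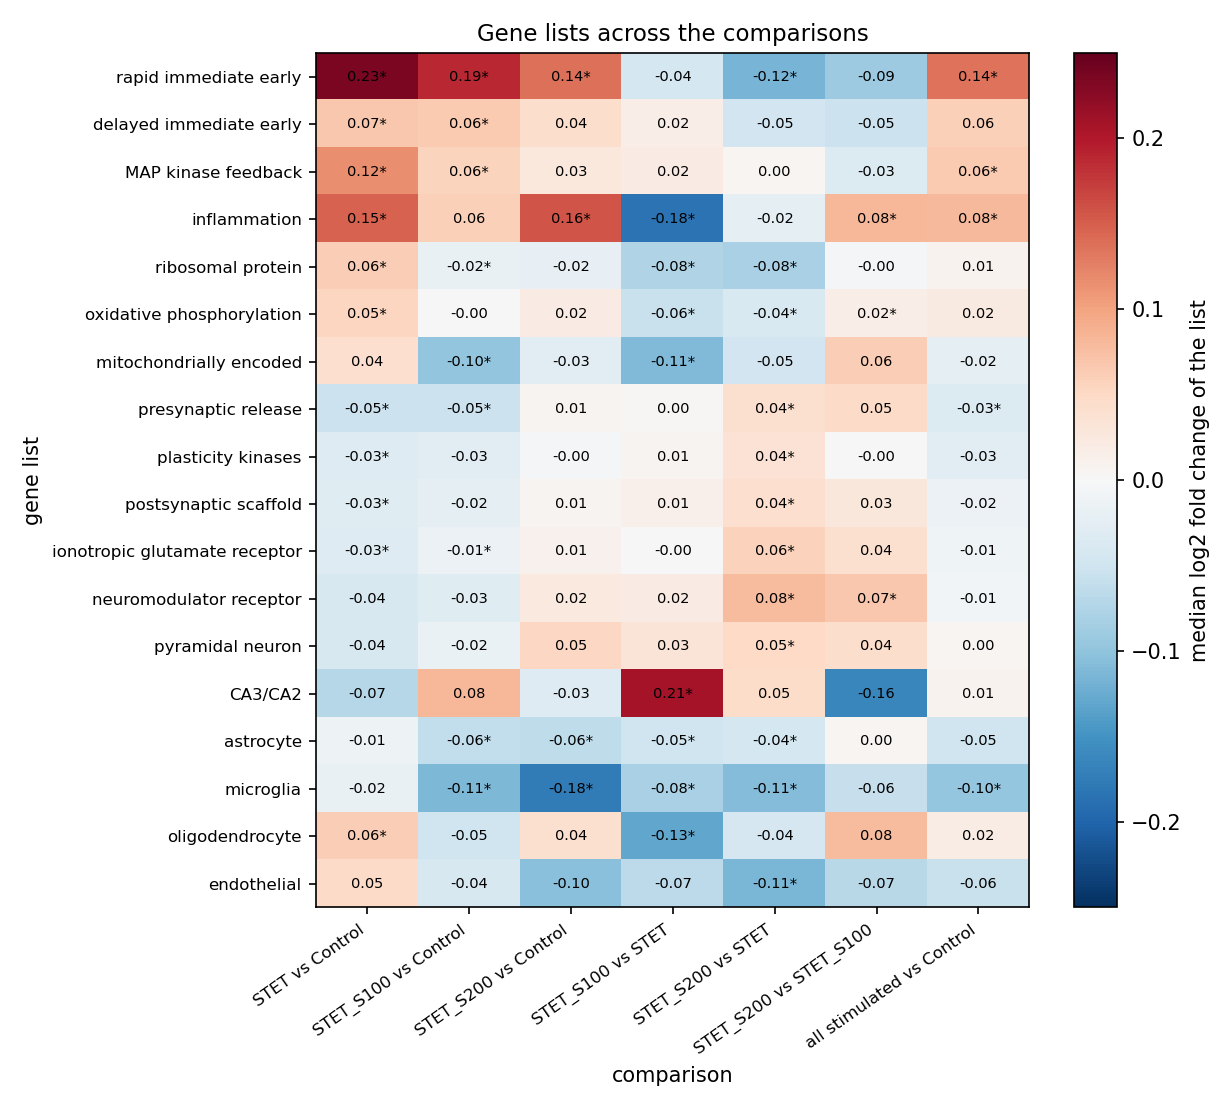
Median log2 fold change (colour and printed value) of 18 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. All of these calls were lost with an estimated correlation, and the ribosomal list runs from 0.06 in STET against Control to −0.08 in STET_S100 and STET_S200 against STET.

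Over all 19492 genes, edgeR called 0 genes at an adjusted p under 0.05 in each of the 7 comparisons. At an unadjusted p under 0.05 there were 683 genes for STET, 1006 for STET_S100, 1154 for STET_S200 and 1066 for all stimulated libraries against Control, and 615 for STET_S100 against STET, 888 for STET_S200 against STET and 1014 for STET_S200 against STET_S100, where chance gives 974.6. These tests do not model the mice that the groups share. DESeq2 called 0, 0, 4, 5, 1, 14 and 5 in the same order, and limma-voom 0 in each. The 14 genes of STET_S200 against STET with DESeq2 included the choroid genes Ttr, Clic6 and Tmem72. Groups did not overlap for 1732 genes (8.89%) in STET against Control, 1972 (10.1%) in STET_S100 and 2147 (11.01%) in STET_S200, where chance gives 10%. With the 7 libraries alone, where STET_S200 is 1 library, genes passed only for all stimulated against Control. They were Myoc, Umod, Gm13340 and the brain noncoding RNA Bc1, which fall outside the naming rule and were named after their values were seen. Umod, a kidney gene, was at 0.718 and 0.382 CPM in Control 1 and Control 2 and at 0 in the stimulated libraries of this set. The kidney gene Slc34a1 was at 0.359 and 0.491 CPM in these Control libraries and at most 0.0951 CPM in those stimulated ones. Outside this set, Umod was at 0.477 CPM in the stimulated library STET 3 and at 0 in Control 3. Slc34a1 was at 0.521 CPM in STET 3 and 0.246 CPM in Control 3. Umod was thus neither confined to Control libraries nor present in each of them. At these levels, under 1 CPM, a response to stimulation cannot be told apart from kidney RNA held by some of the libraries.

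Among the 47 lists, camera with the preset correlation called 12 for STET, 11 for STET_S100, 7 for STET_S200 and 6 for all stimulated libraries against Control, and 8, 16 and 4 for STET_S100 against STET, STET_S200 against STET and STET_S200 against STET_S100. With an estimated correlation and with fry as a directional test 0 lists passed in each comparison, at smallest adjusted p from 0.646 to 0.967 with an estimated correlation. Fry as a test in either direction called 1 list, the pyramidal neuron markers, for STET_S200 against Control (adjusted p = 0.0456) and against STET (adjusted p = 0.0331), where Neurod2 was the gene with the smallest p, and 0 lists in the 5 other comparisons. Calls that held without each library in turn numbered 4, 1, 2 and 1 in the comparisons with Control and 3, 2 and 1 in the others. The 4 in STET were the ribosomal, rapid immediate early, oxidative phosphorylation and presynaptic lists, and the rapid immediate early list was the 1 in STET_S100 and in all stimulated libraries. The counts moved by over 1.5 times without STET 2 (6) and Control 2 (7) for STET, without STET_S100 2 (2) and Control 3 (7) for STET_S100, and without Control 1 (12) and Control 3 (11) for STET_S200. They also did so without Control 1 (11) and STET_S100 2 (3) for all stimulated libraries, without STET 1 (26) and STET 3 (10) for STET_S200 against STET, and without STET_S100 1 (7), STET_S100 3 (13), STET_S200 1 (16) and STET_S200 2 (9) for STET_S200 against STET_S100.

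The stimulated groups shared their Control libraries, and the comparisons were set side by side with that in view. Genes at an unadjusted p under 0.01 in the same direction numbered 21 for STET and STET_S100, 14 for STET and STET_S200 and 40 for STET_S100 and STET_S200 against Control, and 32 for STET_S100 and STET_S200 against STET. Independent lists would share 0.497, 0.636, 1.06 and 0.418 genes, whereas simulated unchanged groups against the same controls shared means of 22.1, 24.0, 22.3 and 24.9 and at most 31, 31, 29 and 37. Past the adjusted threshold 0 genes were shared in each pair, since edgeR called 0. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.643, 0.233, 0.0360 and −0.0723 against simulated values of 0.503, 0.506, 0.512 and 0.503. By rank the values were closer to the simulated ones, with a Spearman rho of 0.559, 0.465, 0.479 and 0.359 against 0.469, 0.467, 0.466 and 0.461. The overlaps of 21, 14 and 32 lay under the simulated maxima, so the shared libraries alone may give them. That of 40, for STET_S100 and STET_S200 against Control, exceeded its maximum of 29. The simulation drew each gene independently, with no differences between libraries shared by many genes. It therefore cannot tell whether the excess is a response. Part of that overlap may also come from the shared libraries, since 3 controls cannot be split between the groups.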

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

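The splits of the libraries by number of lists were planned, and the splits by number of genes and all tests of the ribosomal, choroid plexus and peripheral-tissue patterns were chosen only after the result was seen.

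Ribosomal protein transcripts stood out because they moved in opposite directions over Control, up in STET and down in STET_S100, with medians of 0.06 and −0.02 and a median difference of −0.0755 on the log2 scale (camera adjusted p = 3.2e-23 with the preset correlation for STET_S100 against STET, and adjusted p = 0.967 with an estimated correlation). The fall over Control in STET_S100 (adjusted p = 0.0427, and adjusted p = 0.984 with an estimated correlation) was lost without Control 1 (0.0863), Control 3 (0.161), STET_S100 2 (0.974, where the median turned to 0.00498) or STET_S100 3 (0.0727), with the replicate number as a block (0.0512) and with the choroid score (0.0654). Gene length, GC content and expression level were looked at with 10000 lists matched for them. The median of STET against the mean of the other groups (0.0790) lay at percentile 100 of these lists, whose median was 0.0149. The matched genes were longer, though, at a median of 1256 bases against 1059 for the ribosomal genes. They were also drawn singly, without the correlation between genes of a list. So the median exceeded that of such lists, but these properties are not excluded. Depth does not account for it alone, as STET and STET_S100 differed by 0.00958 M counts in the mean. Differences between libraries unrelated to the groups remain open, since a permutation test of the 4 groups gave p = 0.0615 for the ribosomal score, and so does a response to the amygdala stimulation, which was not tested by itself.

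Choroid plexus transcripts were low in all 3 STET_S200 libraries and in STET_S100 3. They may come from choroid plexus tissue left on the dissected slices in varying amount, since 7 other choroid genes followed Ttr over the 12 libraries with a median Pearson r of 0.981 and a median Spearman rho of 0.979 (permutation p of at most 8.0e-05, also after adjustment over the 7 genes). The median r was 0.978 without the 2 libraries farthest from the median of Ttr and 0.976 without the STET_S200 libraries. A response to the 200 Hz stimulation cannot be told apart from this, because the STET_S200 score lay −3.81 from Control on the log2 scale while libraries of 1 group (STET_S100) spanned 5.89. Dissection that differed by chance between groups of 3 would give the same values.

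Transcripts of fat and epithelium appeared together in Control 3, STET 3, STET_S100 1, STET_S200 2 and STET_S200 3. Liver transcripts joined them, but hardly in STET 3, where Alb was at 0.0868 CPM, Ahsg at 0.0217 CPM and Fgb at 0.0434 CPM. In the other libraries of this set Ahsg was at 0.666 to 1.01 CPM and Fgb at 0.199 to 0.273 CPM. The liver gene Apob, at 0.130 CPM in STET 3, still lay above the 7 libraries outside the set. RNA or reads of other samples could be the source, but the test was undecided. The summed CPM of 20 markers not printed in a first look was 23.8 in the lowest of the 5 libraries and 24.0 in the highest of the 7 others, a ratio of 0.990 (exact permutation p = 0.00505), whereas a first version with 32 markers, some of them already seen, gave 1.38. The 7 others held 20.2 to 24.0 CPM of this sum, so reads present in all libraries limit the test. Of all 40 markers, some of them already seen, 14 were higher in each of the 5 libraries than in each of the 7. These include Fabp4, by which the 5 libraries were set apart, so its place among them was fixed in advance. Tissue of the same male mice is argued against by Xist, which all 5 libraries held above the 7 others (exact permutation p = 0.00126, the smallest that 792 splits can give), but it stays open because Xist lay under 1 CPM, with 0.260 in the lowest of the 5 and 0.207 in the highest of the 7. No biological explanation was tested, since the groups do not part these libraries.

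For the 6 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real grouping called 12 lists for STET against Control and the highest other split 16, with 6 of 10 splits as high. The values were 11 and 20 for STET_S100 against Control (6 of 10), 7 and 17 for STET_S200 against Control (9 of 10), 8 and 18 for STET_S100 against STET (9 of 10), 16 and 20 for STET_S200 against STET (2 of 10) and 4 and 17 for STET_S200 against STET_S100 (10 of 10). For all stimulated against Control, 89 of 100 drawn splits called at least the 6 lists of the real grouping, the highest other 21, so chance cannot be excluded as the origin of that number of lists. By number of genes the real grouping called 0 in each comparison, so all 10 splits, or all 100 for all stimulated against Control, were as high, an outcome fixed by the 0. The highest other splits called 7 genes in each comparison with Control, 246 for STET_S100 against STET, 0 for STET_S200 against STET and for STET_S200 against STET_S100, and 19 for all stimulated. The splits with 246 and 19 genes point to a structure of the samples other than the groups. The first set STET 1, STET 3 and STET_S100 3 against STET 2, STET_S100 1 and STET_S100 2, which parts the libraries of these 2 groups low and high in choroid plexus transcripts. The second set Control 2, STET 2 and STET_S100 2, the libraries numbered 2 of 3 groups, against the 9 others, so mice shared between equal numbers stay open as a source beside choroid content. The 9 others include STET_S100 1, which held more Ttr (1841 CPM) than Control 2 (1167 CPM).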

How the results depend on the processing

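The term for peripheral-tissue RNA, the choroid plexus score, both together, the 7 libraries alone and DESeq2 with its default filtering level were added after the data were seen, and the other settings were chosen before. All of those were run. For 361 pairs of a gene and a comparison, 8122 of 8171 values kept their direction, and 49 reversed. RLE and upper-quartile scaling, the mean count filter, limma-voom, robust = FALSE, the compared groups alone and both block fits reversed no gene. Of 996 list values 635 kept direction and threshold and 14 reversed in the direction of the test. Unless stated, the cause of a change was not tested. The single library left in a group under some settings is assumed to vary like the others. The self-test at the same size recovered most genes changed 1.5-fold, but it held no differences between libraries shared by many genes. In the data Arc, 2.67-fold higher in STET than in Control, did not pass. The self-test therefore does not give the share of changed genes recovered here.

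Counts are given in the order STET, STET_S100 and STET_S200 against Control. Genes past the threshold, 0 with edgeR, numbered 16, 42 and 69 without a filter, with 22 for STET_S100 against STET, 34 for STET_S200 against STET, 98 for STET_S200 against STET_S100 and 52 for all stimulated. In that fit 85.5% of genes had infinite prior degrees of freedom, and other splits for STET_S200 called 0 to 475. DESeq2 called 4 for STET_S200, 1, 14 and 5 for the later pairs and 5 for all stimulated, and with its default filtering level 4, 4, 1, 7, 5 and 10 for STET_S100, STET_S200, the later pairs and all stimulated. The peripheral-tissue term called 2 for STET, 1 for STET_S200, 1 for STET_S100 against STET, 1 for STET_S200 against STET and 4 for all stimulated, and both terms 2, 2 and 2, then 1, 1 and 7 in the same order. The compared groups alone called 1 for STET_S100, Bc1, and the 7 libraries 4 for all stimulated. A threshold of 0.1 called no more genes.

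Rapid immediate early genes adjusted over the list alone (2, 3 and 0) numbered 10, 10 and 7 with DESeq2 at either filtering level, 12, 9 and 6 with limma-voom, 12, 11 and 8 with robust = FALSE, 14, 0 and 12 for the compared groups alone, and 9 and 3 without a filter for STET and STET_S200. Sample quality weights gave 7 for STET and 3 for STET_S200. With the replicate number as a block the counts were 1 for STET and 1 for STET_S200, and the block in limma-voom gave 13, 10 and 7. Whether equal numbers mark the same mice was left open, since 8 of 18 pairs with the same number correlated above 0.1, from −0.370 to 0.483, and 6 of 12 libraries did best with their own number. The peripheral-tissue term gave 11, 10 and 9, the choroid score 0 and 0 for STET and STET_S100, both terms 9, 10 and 10, and the 7 libraries 11, 13 and 3. 

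Lists past the threshold (12, 11, 7, then 8, 16, 4 and 6) were 0 in all comparisons with an estimated correlation and with fry as a directional test. The replicate block gave 5 for STET_S100, the lists it ended being given with their calls, the peripheral-tissue term 11 for STET_S200, the choroid score 2 for STET_S200 against STET and 2 for STET_S200 against STET_S100, both terms 4 and 2, and the 7 libraries 5 for STET, 7 for STET_S100, 8 for STET_S200 against STET and 9 for STET_S200 against STET_S100. Overlaps of genes at an unadjusted p under 0.01 were 21, 14, 40 and 32 for the 4 pairs of comparisons, beside 0 at the adjusted threshold, and 24, 23, 45 and 33 with the block.

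Leaving out 1 library gave 0 to 2 genes for STET_S200, 0 to 8 for STET_S200 against STET_S100, 0 to 1 for all stimulated and 0 to 0 for the other 4 comparisons. Rapid immediate early genes over the list alone ran 0 to 7, 0 to 14 and 0 to 1, and 0 to 14 for all stimulated. Lists ran 6 to 16, 2 to 16 and 6 to 12, then 7 to 8, 10 to 26, 3 to 16 and 3 to 11. Bdnf ran −0.131 to 0.214 for STET, −0.171 to 0.174 for STET_S100, −0.268 to 0.0801 for STET_S200 and −0.190 to 0.156 for all stimulated, Homer1 −0.122 to 0.0311, −0.0670 to 0.0538, −0.0835 to 0.0396 and −0.0909 to 0.0298, and Fosb −0.0161 to 0.0927 for STET_S200.

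Values whose direction reversed outside the fits without 1 library were these, as log2 fold changes or list medians. With the choroid score the choroid list turned to 0.226 for STET_S200 against Control, 0.328 against STET and 0.149 against STET_S100, as that term takes up its signal. For STET_S200 against STET the inhibitory synapse list turned to −0.00618, Atf3 to 0.0294 and Clu to 0.00827, and presynaptic release turned downward in the test at a median of 0.00532, with Ttr 0.0974 against STET_S100 and Homer1 0.00885 against Control. With both terms the choroid list gave 0.211, 0.310 and 0.151, the rapid immediate early list 0.0462, presynaptic release 0.00563 (downward in the test), Atf3 0.0647 and Clu 0.0432 against STET, Ttr 0.0223 against STET_S100, and against Control Bdnf 0.0190 and Homer1 0.0401 for STET_S200 and Homer1 1.4e-05 for all stimulated. The peripheral-tissue term gave Bdnf 0.0548 and Homer1 0.0179 for STET_S200. Sample quality weights gave Bdnf −0.00617 and Homer1 −0.00442 for STET_S100 and Fosb −0.0113 for STET_S200. With the 7 libraries the reactive astrocyte list gave −0.0839 for STET, the astrocyte list 0.0231 for STET_S200 and 0.101 against STET, the microglia list 0.0620 against STET, Bdnf −0.156, −0.0905 and −0.0937 for STET, STET_S100 and all stimulated, Inhba −0.0236 for STET, and Homer1 −0.0701 and 0.0405 for STET_S100 and STET_S200. The sign of the median alone turned, with the direction of the test kept, for the oligodendrocyte list in STET without Control 2 (−0.000709), the ribosomal list in STET_S100 without STET_S100 2 (0.00498) and the astrocyte list in STET_S200 against STET without STET_S200 3 (0.00356), and with the 7 libraries for the delayed list in STET (−0.00328) and the inflammation list in STET_S100 against STET (0.0174). For STET_S200 against STET the 7 libraries gave Gria3 −0.0362, Gja1 0.0416, S100b 0.0475 and Clu 0.0432.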

Other observations

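The list tests were planned, and the single libraries low in dentate gyrus markers and the relation between peripheral-tissue RNA and activity-regulated genes were looked at only after the values were seen.

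Several lists did not pass between all stimulated libraries and Control. CA1 markers had a median log2 fold change of −0.025 (10 genes, camera adjusted p = 0.717), dentate gyrus markers −0.024 (13 genes, 0.827) and interneuron markers −0.001 (17 genes, 0.828), and 0 of their genes passed adjusted over the list alone. For the dentate gyrus the median hides 2 libraries that stood apart, Control 3 with a score of 3.50 and STET_S200 3 with 3.14, against 3.74 to 4.35 in the 10 others. Prox1, a transcription factor of granule cells, was at 19.0 and 16.5 CPM in these 2 and at 34.6 to 61.4 CPM elsewhere. Inhba (8.88 and 10.9 CPM against 12.9 to 24.8) and Bdnf (44.8 and 49.5 CPM against 55.5 to 78.9) were lowest in them too. The amount of dentate gyrus in the dissected area was not tested as a cause, and the inflammation, delayed and MAP kinase calls over Control ended without Control 3. Potassium channel genes (median −0.013, adjusted p = 0.304), neuropeptide genes (0.005, 0.696) and heat shock genes (0.002, 0.659) did not pass either. Glucocorticoid-responsive genes had a median of −0.023 over Control (adjusted p = 0.860), and −0.11 for STET_S200 against STET, where they fell (adjusted p = 0.00754, and adjusted p = 0.646 with an estimated correlation). That last call ended without STET 2 (adjusted p = 0.0873) or STET_S200 2 (adjusted p = 0.0526), with the choroid score (adjusted p = 0.819) and with the 7 libraries (adjusted p = 0.391).

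The score of the rapid immediate early list was lower in the 4 stimulated libraries with peripheral-tissue RNA than in the 5 without, by −0.231, and by −0.141 in STET, −0.397 in STET_S100 and −0.156 in STET_S200. The delayed list was not compared in this way. Shuffling within groups gave an exact permutation p of 0.0370, the smallest that the design allows. The pyramidal marker score differed by −0.0264 (exact permutation p = 0.556). In Control the score was 5.83 in the library with such RNA and 5.89 in the mean of those without.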
